A study of Mus musculus with 4 samples.

How the data were processed

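Lung macrophages of female MMTV-HER2 mice and wildtype FVB mice were profiled by droplet single-cell RNA sequencing at an early stage (16 weeks) and a late stage (32 weeks). MMTV-HER2 mice carry the HER2 oncogene under a mammary tumour virus promoter and develop mammary tumours. The 4 libraries were wildtype early, HER2 early, wildtype late and HER2 late, with 1 library per group. Groups were taken from the sample titles alone, since the strain entry in the labels gives both genotypes for every sample. How many mice went into each library, and which antibodies set the sort gate, is not given in the sources used here. Lungs were digested with collagenase at 37 degrees and the cells were sorted, per the labels' protocols, which name a 10x 3′ assay as version 1.2.

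The authors deposited UMI counts per gene and barcode for every barcode of the 10x list, with no cell filter applied. Alignment used Cell Ranger 5.0.1 and mm10 per the submitters' processing notes, while the count files name Cell Ranger 4, per the file headers. Those files list 32285 genes. The authors also deposited a table per stage of average signal over AM cells, scaled so that each column sums to 10000 over 15906 genes. How the authors chose and averaged those cells is not given in the sources used here.

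A barcode was kept as a cell with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Total UMIs per library were 34858960 in wildtype early, 28786682 in HER2 early, 30587008 in wildtype late and 39228655 in HER2 late. The mitochondrial limit removed 21.0, 17.0, 13.3 and 12.8% of the barcodes that passed the other limits, in the same order. Scrublet, as run in Scanpy 1.11.5 with an expected doublet rate of 6%, marked 1, 0, 2 and 0 cells. That is under the share at which such a caller can be said to have worked, so doublets were largely left in. An alternative without cells of a doublet score over 0.25 was added after seeing the data. Of the kept barcodes 22255 cells entered clustering.

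Cells of all libraries were scaled to 10000 UMIs and log transformed, and 2000 variable genes were chosen, without mitochondrial and ribosomal protein genes, Gm42418 and Xist. The first 30 principal components gave 20 nearest neighbours per cell. Leiden clustering (leidenalg 0.10.2) of their overlap at resolution 1.0 gave 24 clusters, with no integration of libraries. Clusters were named from marker lists of 19 cell types fixed before the data were examined, while the scoring limits were set afterwards. Clusters 0 to 6, 8, 11, 12 and 19 were AM-like (alveolar macrophage-like), and clusters 7 and 16 were IM-like (interstitial macrophage-like). Cluster 13 stayed unnamed because its leading genes (Ccl17, Cd207) held no marker of the best-scoring type. Cluster 14 stayed unnamed for its doublet scores, cluster 20 because 32 of its 33 cells came from wildtype early, and cluster 23 for its size of 1 cell. Where present, these held between 0.0184 and 1.27% of a library's cells each.

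UMI counts were summed per library and class and expressed as CPM, the count of a gene scaled to the UMI total of that class in that library. Folds are ratios of CPM with exact conditional binomial 95% intervals, and shares carry exact Clopper-Pearson 95% intervals. Both cover counting error only. No test, p-value or standard error was computed, because cells are not replicates. Genes were named by a rule fixed before the data were examined. For each HER2-over-wildtype comparison it took the 12 highest and the 12 lowest folds, ranked by the interval bound nearest to 0, among genes with at least 50 CPM in either library. For late over early it took 6 and 6, and for both stages together the 10 highest and 10 lowest by the smallest of the 4 cross ratios. Mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes, unnamed gene models, Xist, Y-linked genes and markers of other cell types were left out of the ranking.

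For each of 20 fixed gene lists, the median log2 fold (pseudocount 1 CPM) of members with at least 10 CPM was taken, less the median of all such genes. Its percentile among 10000 random lists of the same size, matched on expression in 20 bins, describes these libraries and is no test. Members at least 1.25-fold higher or lower were counted. The spread of a pair of libraries is the SD of log2 folds over genes with at least 50 CPM in the mean of the 4 libraries, computed for all 6 pairs. Cells in cycle are those with at least 3 UMIs of the cell cycle list after thinning every cell to 2000 UMIs. Free RNA was taken from barcodes with 10 to 100 UMIs. It was set at 1.64 to 2.81% of AM-like and 1.32 to 4.02% of IM-like UMIs. Near-identical copies of a gene were sought by BLAST 2.17.0 of its last 300 transcribed bases against the transcripts of GENCODE release M21, at 95% identity or more over at least 90 bases. Gene positions are from the same release (GRCm38, the assembly also called mm10).

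The calculations were tested on simulated counts drawn at the real means and totals with 200 genes changed. For AM-like early (2542 genes) the interval held the true value for 95.0% of unchanged genes, and every gene changed by 1.25-fold had an interval clear of 0. For IM-like early (2764 genes) that was so for 56.0% of genes changed by 1.25-fold, 82.0% of those changed by 1.5-fold and all of those changed by 2-fold. Alternatives covered the cell limits, mitochondrial limit, doublets, resolution, TMM scaling (edgeR 4.0.16, factors only), equal weight per cell, free RNA, thinning, cells in cycle, the CPM minimum and the authors' averages. Those added after seeing the data were the doublet score, cells over 25% Gm42418, the cluster held by 1 library, totals without Gm42418 and removal of a trend with transcript length. Gene folds under alternatives carry a pseudocount of 1 CPM that the main gene folds lack, which shrinks folds of genes with few UMIs. The alternative without cells holding 3 or more cell cycle UMIs used unthinned counts, so it also left out deep cells. In wildtype early it kept 102 of 166 IM-like cells, with 475372 of 962495 UMIs, although 12.6% were in cycle after thinning.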

Results

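Single-cell transcriptomes of sorted lung macrophages were compared between MMTV-HER2 and wildtype mice at 16 and at 32 weeks, to describe alveolar and interstitial macrophages as mammary tumours develop. After filtering, 5448 cells of wildtype early, 5126 of HER2 early, 5127 of wildtype late and 6554 of HER2 late remained. Median depths over the cells passing the limits were 4387, 3801, 4478 and 4463 UMIs per cell. AM-like cells gave 17894007 to 26704318 UMIs per library and IM-like cells 962495 to 3188796. With 1 library per group, no difference below has a replicate check, and the intervals cover counting error only.

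AM-like cells, which held Chil3, Ear1, Ear2, Fabp1 and Plet1 among their leading genes, made up 88.0% of wildtype early cells (95% interval 87.1 to 88.9), 85.4% of HER2 early (84.4 to 86.3), 81.5% of wildtype late (80.5 to 82.6) and 85.9% of HER2 late (85.0 to 86.7). IM-like cells, led by C1qa, C1qb, C1qc and Cx3cr1, made up 3.05% (2.61 to 3.54), 7.86% (7.14 to 8.63), 11.0% (10.2 to 11.9) and 9.002% (8.32 to 9.72) in the same order. T cell-like cells were 5.30% of wildtype early, against 1.35, 1.56 and 0.58% in the other libraries. Endothelial, B cell-like, fibroblast-like, NK cell-like, epithelial and non-classical monocyte-like cells each stayed at or below 2.03%. The cells were sorted, and the gate can set all of these shares. Not every AM-like cluster was led by the genes above. Cluster 1, with 14.1 to 18.4% of AM-like cells, was led by Gm26917, Gm15564 and Gm42418 beside Chil3. Its cells had medians of 2300 UMIs and 35.35% Gm42418. Clusters 11 and 12 were led mainly by cell cycle genes. Gm42418 took 16.7 to 19.9% of AM-like UMIs.

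**Figure D1:**
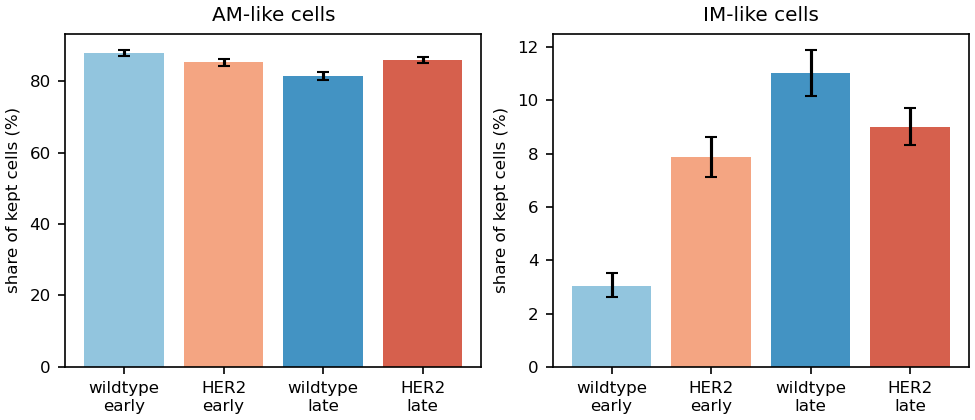
Share of kept cells (percent, vertical axis) that were AM-like (left) or IM-like (right) in each of the 4 libraries, with bars for the share and whiskers for the exact 95% interval of counting error. IM-like cells ranged from 3.05% in wildtype early to 11.0% in wildtype late.

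Labels were checked with Erbb2, the mouse counterpart of the transgene, and with sex-linked genes. Erbb2 (chromosome 11, 98412470 to 98437716) stood at 6.76 CPM in AM-like cells of wildtype early and 11.4 in HER2 early, but at 10.1 in wildtype late and 8.73 in HER2 late. IM-like cells gave 0, 5, 0 and 5 Erbb2 UMIs in wildtype early, HER2 early, wildtype late and HER2 late, where a count of 0 allows up to 3.12 CPM in wildtype early and 1.62 in wildtype late, against 2.73 and 1.57 CPM measured in HER2 early and late. Erbb2 reads do not show the transgene apart from the mouse gene, so they do not check the genotype. Xist was at 962 to 1435 CPM in AM-like cells of all 4 libraries, and Y-linked genes gave 0 to 3 UMIs, for animals labelled female.

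In early AM-like cells, the comparison of HER2 with wildtype showed higher Marco, a scavenger receptor, at 109 against 55.2 CPM (1.98-fold, log2 0.99, 95% interval 0.88 to 1.09). Apoe (1.35-fold), Apoc1 (1.31-fold), Lpl (1.21-fold) and Lipa (1.18-fold), which carry or break down lipids, were also higher, as were Ear2, Gadd45g, Kcnj15, Ubb, Mylip, Gpnmb and Gstm1 at 1.18 to 1.37-fold. Fn1, which encodes fibronectin, was 2.47-fold lower (47.4 against 117 CPM, log2 -1.31, interval -1.42 to -1.19), and the calcium-binding S100a6 2.36-fold lower (log2 -1.24, interval -1.35 to -1.13). Dusp1, a phosphatase of the MAP kinases, was 1.72-fold lower, and the antigen presentation genes Cd74, H2-Aa and H2-Ab1 were 1.46, 1.39 and 1.40-fold lower. Nfkbia, Tsc22d3, Top2a, Egr1, Tgfbi and Rgs1 were 1.41 to 1.47-fold lower. With equal shares for every AM-like cluster, Top2a moved from log2 -0.53 to -0.21, Egr1 from -0.51 to -0.24 and Rgs1 from -0.48 to -0.31. Of the genes higher early, Apoe, Apoc1, Ear2, Gadd45g and Ubb were also higher in HER2 late in the authors' averages. Marco (log2 -0.24), Lpl (-0.54), Lipa (-0.12), Kcnj15 (-0.46), Mylip (-0.12), Gpnmb (-0.53) and Gstm1 (-0.15) were lower there at the late stage.

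Among the fixed lists, 7 of 20 lay outside the range of random lists (its central 95%) in early AM-like cells. The cell cycle list was lower, with a median log2 of -0.25 relative to all genes and below every random list. Of its 24 measured members 11 passed the step set for members on the lower side and none on the higher, led by Cenpf (log2 -0.88) and Ube2c (-0.69). Non-macrophage cells had a median of -1.86 for this list, and 22 of 24 members had the sign they had in AM-like cells. T cell-like cells were 289 of 397 non-macrophage cells in wildtype early and 69 of 238 in HER2 early. That median therefore does not show a shift within a cell type. Cholesterol synthesis was lower too (-0.22, below every random list), with Cyp51 at -0.66 and Msmo1 at -0.43. MHC class II presentation (-0.11, percentile 0.02) and the immediate early and dissociation stress list (-0.05, percentile 0.13) were lower by less. Only 6 MHC class II members were expressed highly enough in non-macrophage cells to compare, a different set from that behind -0.11. Their median, not relative to all genes, was -0.30 in AM-like and -0.51 in non-macrophage cells, and 5 of the 6 had the same sign. Lipid handling (0.11, above every random list), lysosome and efferocytosis (0.08, percentile 99.98) and complement and Fc receptors (0.06, percentile 97.9) were higher, with Cd36 at 0.23, Cd68 at 0.18 and C3 at 0.26. Most members of these 3 lists lay within that step. The stress list came within the range of random lists without cells holding 3 or more cell cycle UMIs, and the complement list did so there, with free RNA subtracted and without the trend with transcript length. Ear2 and Ubb share their 3′ ends with near-identical copies and are uncertain. Airway gene Scgb1a1 stood at 23.9 CPM in HER2 early AM-like cells and 1.56 in wildtype early, and at 862 and 9.27 CPM in the free RNA.

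Counted by at least 3 UMIs after thinning, the share of AM-like cells in cycle did not follow the list. After thinning it was 11.4% (10.5 to 12.4) in wildtype early, 11.1% (10.1 to 12.1) in HER2 early, 11.3% (10.3 to 12.3) in wildtype late and 9.77% (8.98 to 10.6) in HER2 late, leaving out 361, 496, 174 and 347 shallower cells. Without thinning it was 28.6, 24.5, 32.2 and 27.5%. Summed CPM of the list were 1054, 874, 846 and 813. The share of cluster 12, led by Pclaf, Top2a and Rrm2, had the same order as these sums, at 2.21, 1.67, 1.41 and 1.39% of AM-like cells.

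Late AM-like cells of HER2 had higher Hspa1b, a heat shock protein, at 69.4 against 13.8 CPM (5.01-fold, log2 2.33, interval 2.15 to 2.51). The glycolytic enzyme Gapdh was 2.41-fold higher, and Gadd45g, Ear1, Apoc1, Ubb, Bcl2a1b, Ear6, Tmsb10, Ang4, H2afj and Hspe1 were 1.63 to 1.88-fold higher. The ferritin gene copy Ftl1-ps1 was 3.26-fold lower, and Mmp12, an elastase of macrophages, 2.44-fold lower (58.5 against 143 CPM). Htr2c, Rgs1, Lyst, Ogt, Kcnq1ot1, Ccdc80, Hdac4, Dusp1 and Ndufb1-ps were 1.64 to 1.90-fold lower. Gapdh, Ubb, Ear1, Bcl2a1b, Tmsb10, Hspe1 and Ftl1-ps1 share their 3′ ends with near-identical copies and are uncertain, and Hspa1b has the close paralog Hspa1a. Cluster 0 held 59.7% of wildtype late AM-like cells but 10.2% of HER2 late, 2.95% of HER2 early and 2.75% of wildtype early, and Ftl1-ps1, Marco and Gpnmb were among its leading genes. Ftl1-ps1 moved to log2 0.04 once free RNA was subtracted. Non-macrophage cells of the same libraries had late log2 folds of 1.53 for Hspa1b, 1.87 for Hspa1a, 1.20 for Gapdh, 0.90 for Ubb, 0.67 for Tmsb10 and -2.37 for Ftl1-ps1. Bcl2a1b, Hspe1 and Dusp1 also lay on the side they had in AM-like cells. So did Ear1 (256 CPM in HER2 late, 132 in wildtype late), but as a marker of alveolar macrophages it does not speak for other cell types.

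The median of all genes in this late comparison lay at log2 -0.20 over 7176 genes, and list medians, but not the folds of single genes, are given relative to it. The immediate early and dissociation stress list was higher (0.42, above every random list), with 9 of 25 members higher and 4 lower. Hspa1b, Hspa1a (2.30) and Dnajb1 (0.74) stood above, and Dusp1 (-0.75) below. Oxidative phosphorylation was higher (0.42, above every random list), with Ndufb9 at 0.42 and Cox5b at 0.39, but its median was 0.06, within the range of random lists, after a trend with transcript length was removed. Ribosomal protein genes took 8.43% of AM-like UMIs in wildtype late and 10.3 to 10.7% in the other libraries. Cholesterol synthesis was lower (-0.19, percentile 0.24), with Srebf2, a transcription factor of sterol synthesis, at -0.65 and Cyp51 at -0.43. Lysosome and efferocytosis was lower (-0.07, percentile 0.68), with Grn at -0.60 and Cd300lf at -0.61, and the cell cycle list was higher (0.16, percentile 99.55), with Ube2c at 0.74 and Mcm7 at -0.54. Late cholesterol synthesis came within the range of random lists without cells over 25% Gm42418, and the cell cycle list with every cell weighing the same and in the authors' averages.

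**Figure D2:**
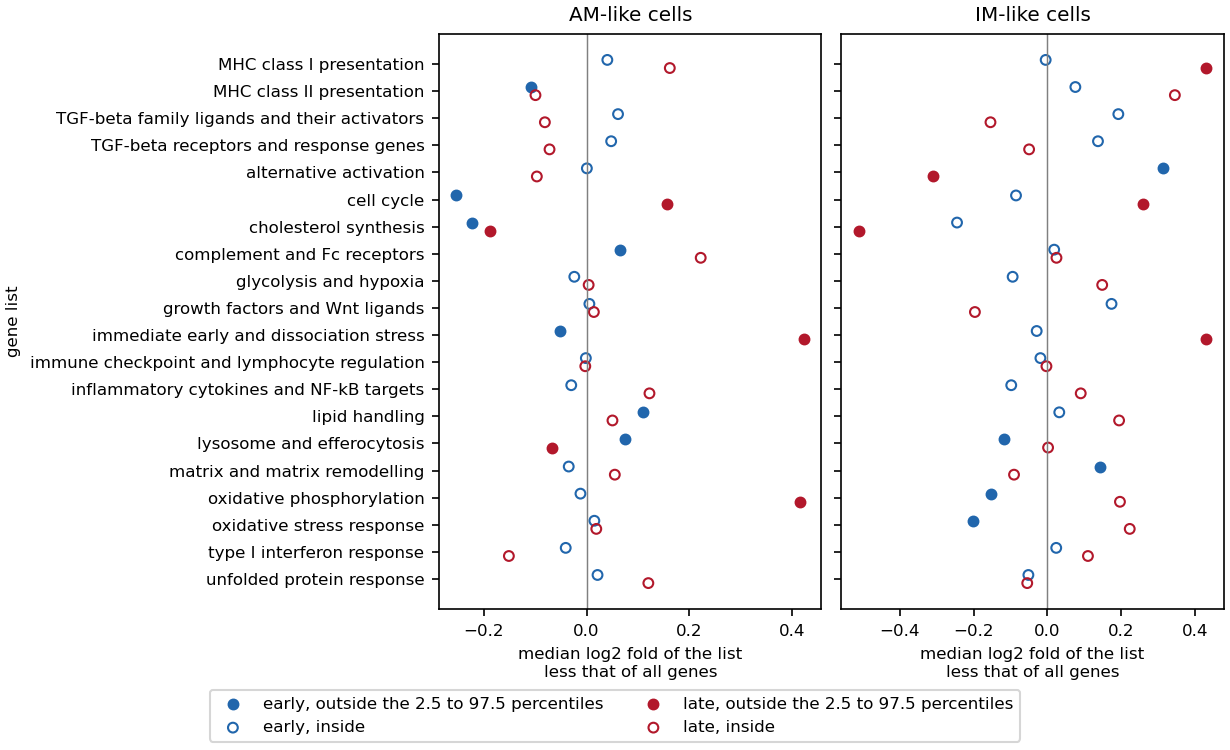
Median log2 fold of each of the 20 gene lists (vertical axis), HER2 over wildtype, less the median of all genes (horizontal axis), in AM-like (left) and IM-like cells (right), early in blue and late in red; filled points lie outside the central 95% of random lists. The stress list lies at -0.05 early and 0.42 late in AM-like cells.

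Folds of the 2 stages were set side by side to find genes that differed by genotype at both. In AM-like cells Gadd45g, Apoc1 and Apoe were higher in both HER2 libraries than in both wildtype libraries, by at least 1.37, 1.31 and 1.248-fold. Dusp1, Rgs1 and the transcription factor Klf9 were lower by at least 1.53, 1.41 and 1.33-fold. Acaa1b, Hint2, Trim25, Amdhd2, Herpud1, Ftl1 and Csnk1e followed among the higher genes and Hivep3, Ccdc80, Ccr1, Fos, Dennd4a, Rin3 and Pfkp among the lower. Over 2608 genes the libraries separated by genotype for 30.3%, where chance gives 33.3%, and by stage for 48.8%. Across genes, early and late folds correlated at Pearson -0.03 in AM-like and -0.12 in IM-like cells (2787 genes), and genes are not independent replicates.

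Genotype folds in AM-like cells spread by an SD of 0.0971 early and 0.281 late, against 0.346 between the stages in wildtype and 0.132 in HER2. Counting error alone gave 0.0446 and 0.0419 for the 2 genotype comparisons in simulated counts. Pairs that include wildtype late had the widest spreads, 0.281, 0.332 and 0.346. IM-like cells spread by 0.245 early and 0.329 late, and counting error alone gave 0.189 and 0.135. The early IM-like spread ranged from 0.184 over genes with at least 200 CPM to 0.399 over genes with at least 10 CPM. The authors' deposited table gave the direction found here for all 24 named genes at each stage, and its folds correlated with the rebuilt ones at 0.922 early and 0.983 late over 2602 genes, of which 80.6% had the same direction early and 95.6% late.

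Between the stages, wildtype AM-like cells had higher Ftl1-ps1, Marco (182 against 55.2 CPM), Mmp12, Mlph, Gpnmb and Kcnj15 late, and lower Hspa1b, Hspa1a, Fn1 (12.4 against 117 CPM), Ubb, Bcl2a1a and Gapdh. Lysosome and efferocytosis (0.23, percentile 99.98) and cholesterol synthesis (0.20, percentile 98.91) were higher relative to the median of 0.16 over 7225 genes, the latter not without cells holding 3 or more cell cycle UMIs. Ftl1-ps1 was at log2 0.89 against 2.96 with free RNA subtracted. Oxidative phosphorylation (-0.47), cell cycle (-0.44) and stress genes (-0.32) were lower, below every random list, and the first of these was -0.08 after the trend with transcript length was removed. Non-macrophage cells had medians of -0.21, -2.09 and -0.50 for these 3 lists, not relative to all genes. Of the members compared, 23 of 27, 18 of 24 and 14 of 23 lay on the side they had in AM-like cells. For cholesterol synthesis the non-macrophage median was 0.45, with 8 of 11 members on the AM-like side, and for lysosome and efferocytosis -0.18, with 5 of 10. T cell-like cells were 289 of 397 non-macrophage cells in wildtype early and 80 of 252 in wildtype late. These medians therefore do not show a shift within a cell type. HER2 AM-like cells had higher Wfdc10, Ftl1-ps1, Ear10, Cd74, Egr1 and Fabp4 late and lower Hspa1b, Ubb, Ear2, Bcl2a1a, Hspa1a and Hmgn2, of which Ear10, Bcl2a1a and Hmgn2 also have near-identical copies. Their cholesterol synthesis (0.27), oxidative stress response (0.13) and stress lists (0.12) were above every random list. MHC class II (0.18, percentile 99.97) was also higher, with Cd74 at 0.63, as were growth factors and Wnt ligands, NF-kB targets, lysosome genes and the unfolded protein response. Over 6 MHC class II members, the median was 0.61 in non-macrophage and 0.29 in AM-like cells, not relative to all genes, with 4 on the same side. Non-macrophage medians for cholesterol synthesis, oxidative stress response and stress genes were 0.03, -0.11 and -0.09.

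Early IM-like cells of HER2 had higher Retnla, a marker of alternative activation (1376 against 796 CPM, log2 0.79, interval 0.67 to 0.91), Ccl12 (2.47-fold) and the interferon-inducible Ifi27l2a (2.01-fold). Dusp1 (2.50-fold), Nfkbia (1.75-fold), Rgs1 (1.92-fold), Vcam1 (2.03-fold) and Lgals3 (1.54-fold) were lower, as were Atp6v1c1, Rbis, Cstb, Id2 and Yipf1. Ccnd2, Itga6, Ccdc152 and Cbfa2t3 were 1.82 to 2.33-fold higher. Cxcl2, a chemokine for neutrophils, was 4.66-fold lower. Ccl12 and Ifi27l2a turned lower when the cluster of 33 cells held almost wholly by wildtype early was counted as IM-like, or with a mitochondrial limit of 20%. Vcam1 then reached up to log2 -2.51 from -1.02, and Retnla was at 0.15 without cells holding 3 or more cell cycle UMIs.

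Several of the widest IM-like folds rested on few cells. All Saa3 UMIs (33.9-fold higher early, 7.71-fold late) lay in 3 cells of each HER2 library, and in 1 cell of wildtype early and 3 of wildtype late. Saa3, Lyz1 and Rbis also have near-identical copies. The 3 richest cells held 94.7 and 94.4% of Prg4 UMIs in the early libraries, 98.9% of Fabp7 UMIs in wildtype early (10.9-fold lower in HER2) and 64.2 and 70.4% of Slpi and Lyz1 UMIs in HER2 early. They held 59.2% of Cxcl2 and 60.3% of Retnla UMIs in wildtype early. In the late libraries they held 54.3% of Ccl4 UMIs in HER2, and 66.6% of Retnla, 66.0% of Mt2, 63.3% of Rcan1 and 51.2% of Ccl8 UMIs in wildtype. Under single alternatives, early log2 folds came to 3.41 for Saa3, 0.74 for Slpi, 0.45 for Prg4, -1.10 for Fabp7 and -1.28 for Cxcl2, and Lyz1 turned lower. For Saa3, at 2.08 CPM in wildtype early, part of the move comes from the pseudocount of 1 CPM that only the alternatives carry.

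Alternative activation was higher in early IM-like cells (0.31, percentile 99.98), with Mgl2 at 0.39 beside Retnla, but -0.06 without cells holding 3 or more cell cycle UMIs. Oxidative stress response (-0.20, percentile 0.04), oxidative phosphorylation (-0.15, percentile 0.01) and lysosome and efferocytosis (-0.12, percentile 0.325) were lower, with Mt2 at -0.83, Cox5a at -0.51 and Ctsd at -0.38. Matrix and matrix remodelling was higher (0.14, percentile 98.93) while its members Fn1 (-0.62) and Mmp9 (-0.41) were lower. Oxidative phosphorylation came within the range of random lists without cells holding 3 or more cell cycle UMIs, the lysosome list under 4 alternatives and the matrix list under 7. Wildtype early had 166 IM-like cells, the fewest of the 4 libraries, and 13 of the 24 genes named at each stage stayed within 1.5-fold of their fold under every alternative run.

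Late IM-like cells of HER2 had higher H2-Aa (1.63-fold), Ccl4 (3.85-fold), Hspa1a (2.56-fold), Hspa1b (2.02-fold) and Rgs1 (1.91-fold), and higher Gapdh, Tmsb10, Bcl2a1b and Ubb, which have near-identical copies. Ear1 and Ear2, markers of alveolar macrophages with near-identical copies, were 5.13 and 3.22-fold higher, but their log2 folds ranged over alternatives from 1.47 to 5.88 and from 0.85 to 5.72, highest with free RNA subtracted. The subtraction cut off negative values, which can widen such folds. The alveolar macrophage marker list as a whole stood at 0.85 (above every random list). Its member Marco was at 31.05 against 10.8 CPM, with 3 cells holding 53.5 and 75% of its UMIs. Doublets were largely left in, so RNA of AM-like cells is not excluded as a source of these markers. Retnla was 2.23-fold lower (log2 -1.15, interval -1.27 to -1.04), and Ccl8, Fcna and Prg4 4.27, 2.29 and 4.95-fold lower. These 4 genes lead cluster 16, which held 4.07% of wildtype late and 3.73% of HER2 late IM-like cells. Rcan1, Ftl1-ps1, Rnf135, Rnf121, Tsix, Etv5, Mt2 and Atp5k were 1.98 to 5.45-fold lower. Retnla and Mt2 turned higher without cells holding 3 or more cell cycle UMIs, and Ftl1-ps1 with free RNA subtracted. The first of these limits kept 390 of 590 HER2 late IM-like cells, with 1790786 of 3188796 UMIs. It does not tell loss of cycling cells from loss of deep cells. Without cells holding 3 or more cell cycle UMIs, Ccl4 was at log2 0.67 against 1.94 and Fcna at -0.45 against -1.19. Under single alternatives the folds came to -1.44 for Prg4, -1.56 for Rcan1 and -1.10 for Rnf135, and Saa3 ranged from 2.15 to 4.58. Deviations of wildtype late from the other 3 libraries correlated between IM-like and AM-like cells at 0.684 across genes, against 0.307 to 0.392 for the other libraries.

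Relative to a median of -0.13 over 7770 genes, MHC class I presentation was higher in late IM-like cells (0.43, above every random list), with H2-T23 at 0.89 and Psmb9, a subunit of the immunoproteasome, at 0.68. Stress genes were higher (0.43, above every random list), and so was the cell cycle list (0.26, percentile 98.8), though not from 2000 UMIs per cell or without cells holding 3 or more cell cycle UMIs. Cholesterol synthesis was lower (-0.51, below every random list), with 12 of 13 members past the step on the lower side, among them Stard4 at -1.15 and Fdps at -0.94. Alternative activation was lower (-0.31, percentile 0.06), with Ccl24 at -0.81 and Mrc1 at -0.66 but Chil3 at 0.68. Chil3 and Mrc1 are also on the alveolar macrophage marker list. Non-macrophage cells of the same libraries had medians, not relative to all genes, of 0.67 for MHC class I, 0.33 for stress genes and -0.49 for cholesterol synthesis. Single cells supplied foreign transcripts here: 94.96% of Hbb-bs UMIs in HER2 late and 99.0% of S100a9 UMIs in wildtype late came from 1 cell each.

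In IM-like cells the libraries separated by genotype for 26.2% of 2787 genes, where chance gives 33.3%, and by the crossed grouping for 29.0%. Genes higher in both HER2 libraries of IM-like cells, after Saa3, were H2-M3, Cxcl14, Dapp1 and the interferon signalling factor Irf9, by at least 1.64, 1.55, 1.44 and 1.36-fold. Mt2, Birc3, Tomm70a and Sulf2 were lower by at least 1.501, 1.44, 1.43 and 1.40-fold. For Mt2 this rests on few cells, since 3 cells held 58.3% of its UMIs in wildtype early and 66.0% in wildtype late, and its late fold moved by over 1.5 times under 5 alternatives and turned to 0.27 under 1 of them. From early to late, Mmp12 and Mmp13, both matrix proteases, were higher in IM-like cells of both genotypes, Mmp13 at 137 against 29.1 CPM in wildtype and 143 against 40.4 in HER2. Cxcl13, a chemokine for B cells, was lower in both (211 against 798, and 119 against 729 CPM). In wildtype, 3 cells held 58.1% of Cxcl13 UMIs early and 47.2% late, and the log2 folds over stages ranged over alternatives from -2.53 to -1.40 for Cxcl13, from 1.32 to 2.46 for Mmp12 and from 1.89 to 2.92 for Mmp13. In wildtype, stress genes (-0.69), NF-kB targets (-0.53), cell cycle (-0.49) and MHC class I (-0.44) and oxidative stress genes (-0.30) were lower late and TGF-beta ligands and activators higher (0.50, percentile 98.54). Of these 6 lists, 1 (MHC class I) stayed outside the range of random lists under every alternative run, and of the 5 in HER2, 3 did. In HER2, MHC class II was higher (0.25, percentile 99.98), as were TGF-beta ligands and activators (0.26, percentile 98.75), and the immune checkpoint list (0.16, percentile 98.95), while alternative activation (-0.19, percentile 0.36) and stress genes (-0.17, below every random list) were lower. Cluster 16 held 12.05% of wildtype early and 10.2% of HER2 early IM-like cells, against 4.07 and 3.73% late.

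TGF-beta ligands, signalling proteins that macrophages secrete, were among the genes fixed for measurement before the data were examined. Tgfb1 (chromosome 7, 25687002 to 25705077) was at 269, 276, 288 and 279 CPM in AM-like cells of wildtype early, HER2 early, wildtype late and HER2 late, and at 233, 231, 331 and 304 CPM in IM-like cells. Tgfb2 was at 4.32, 3.41, 0.62 and 2.51 CPM in AM-like cells, with a UMI in 0.24 to 1.29% of cells. Lymphocyte-like cells, of which 289 in wildtype early were T cell-like, with median depths of 2415 to 5052 UMIs against 3704 to 4723 in AM-like cells, held one in 0 to 0.97% of cells. The share with a Tgfb2 UMI was 0.68 to 1.74% in IM-like cells. It was 1.61 to 7.32% in endothelial cell-like cells, at median depths of 4112 to 6832 UMIs. Tgfb3 gave 0, 0, 3 and 0 UMIs in AM-like cells, where 3 UMIs make 0.168 CPM in the library with the fewest. Marco lies on chromosome 1 (120474538 to 120505024), as does Fn1 (71585520 to 71653200), and S100a6 on chromosome 3 (90612882 to 90624181).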

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

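Tests on thymocyte genes and on transcript length were chosen only after their results were seen. The tests of a library-wide difference, gene copies, cluster mix, free RNA in the early comparison and doublets were fixed before their values but after the patterns were known. Each difference between the stages below was picked because these values lay on opposite sides of 0, for genes by a minimum fold set after the data were seen, and none was tested, since each stage has 1 library per genotype.

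Genotype folds of genes, and medians of lists relative to all genes, lay on opposite sides of 0 at the 2 stages for several genes and groups. In AM-like cells the late less early difference was 2.39 for Fn1 (log2), 0.48 for the stress list, 0.41 for the cell cycle list and -0.14 for lysosome and efferocytosis. The cell cycle list was opposite only relative to all genes, as its own median was -0.28 early and -0.04 late, and its late value came within the range of random lists under 2 alternatives. In IM-like cells it was 3.48 for Ccl4, -3.60 for Prg4, -1.94 for Retnla, 1.88 for Rgs1 and -0.62 for alternative activation. Without cells holding 3 or more cell cycle UMIs, the opposition was absent for Retnla (0.15 early, 0.0944 late) and alternative activation (-0.0574 early). In wildtype early, 3 cells held 94.7% of Prg4 and 68.3% of Ccl4 UMIs.

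The AM-like cells of wildtype late stood apart from those of the other 3 libraries, with a spread of 0.281 against HER2 late where HER2 and wildtype early differed by 0.0971. Gene copies are argued against as the whole cause, since the SD of its deviations was 0.921 times as large over genes with no near-identical copy. Over 202 genes with copies the SD was 0.467 and the median deviation -0.144, against 0.288 and 0.156 over 2405 genes without. Whether copies are a part of the cause stays open. Transcript length is argued against as the whole cause, since the SD was 0.874 times the original once the trend was removed, and whether it is a part stays open. The deviations of AM-like and non-macrophage cells correlated across genes at 0.536 in wildtype late (0.238 to 0.292 in the others), and those of AM-like and IM-like cells at 0.684 (0.307 to 0.392), so a difference in library making or handling that acts on every cell type may contribute. Age and genotype stay open and untested, because wildtype late is a single library.

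The length test was first set as a Spearman correlation at least 2 times that of every other library, which gave 0.464 in wildtype late and -0.532 in HER2 late and could not decide, as the other libraries' deviations contain wildtype late; the SD ratio replaced it after that result. Free RNA was also tried as an explanation of the same pattern and left the late spread at 0.283. An earlier choice of pattern, Saa3 in IM-like cells, was dropped after its tests, when it proved to rest on 3 cells in each HER2 library: free RNA predicted 1.09 and 2.41% of its CPM there, 0 of these cells had a doublet score over 0.25, and 300 of the HER2 UMIs lay in cluster 16.

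T cell-like cells of wildtype early held thymocyte genes. They entered no fold of AM-like or IM-like cells, but they are among the non-macrophage and lymphocyte-like cells used as references, whose folds are given. A UMI of Rag1, Rag2, Ptcra, Dntt or Arpp21 was in 57.1% of these 289 cells (51.2 to 62.9), against 4.35, 6.25 and 0% in the other libraries. Mature T cells as the only source are argued against by Cd4 UMIs in 68.5% of the cells that held Cd8a or Cd8b1, and free RNA by a share of 0.459% in AM-like cells. The same Cd4 measure was 30.8% in HER2 early (4 of 13 cells), 26.3% in wildtype late (5 of 19) and 12.5% in HER2 late (1 of 8). This sign thus also occurred where thymocyte genes were rare. Thymus tissue carried along with the lung is a candidate source, as a hypothesis found on the same data. Whether IM-like cells of wildtype early share this source was not tested. A biological explanation was not tested.

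In early AM-like cells Fn1, S100a6 and MHC class II genes were lower and Marco and Apoe higher in HER2. With equal shares for every AM-like cluster, the median absolute fold of the 24 named genes was 0.829 times the original, only just above the bound of 0.8 set for excluding it, and Fn1 moved from -1.29 to -1.24 and Marco from 0.97 to 0.94, which argues against another mix of clusters as the whole cause for these genes. It stays open for Top2a (-0.53 to -0.21) and Egr1 (-0.51 to -0.24). Subtracting free RNA gave 1.02 times and leaving out cells of high doublet score 1.01 times. All 24 genes kept their direction in each of the 3 tests. The doublet filter kept 4727 of 4796 wildtype early and 4348 of 4377 HER2 early AM-like cells. It could therefore hardly move the folds and decides nothing about doublets. The late stage did not repeat the pattern for Marco (154 CPM in HER2 against 182 in wildtype) or Fn1 (26.3 against 12.4). In the authors' averages Apoe was again higher late (log2 0.59) and S100a6 again lower (-0.50). Cd74 (-0.08), H2-Aa (0.43) and H2-Ab1 (0.14) were mixed there. Genotype and a difference between single libraries or animals cannot be told apart here.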

How the results depend on the processing

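Removal of the trend with transcript length, totals without Gm42418, limits on Gm42418 and doublet scores, and keeping the cluster of 1 library were tests chosen after seeing the data. No paired analysis was possible because there is 1 library per group. Of the class shares and, for AM-like cells only, the genotype spreads, early-late correlation and cycling shares recomputed under alternatives, 28 values moved and 102 stayed within the main interval, within 10% (spreads) or within 0.1 (correlation), tolerances set after the data were seen. Without cells over 25% Gm42418, AM-like shares were 84.5, 80.9, 78.2 and 80.3% and IM-like shares 3.98, 10.3, 12.96 and 12.7% (wildtype early, HER2 early, wildtype late, HER2 late); AM-like cells hold more Gm42418, so the filter removes them first. With the cluster of 1 library kept, wildtype early IM-like cells were 3.63%. HER2 late IM-like cells were 9.90% from 500 UMIs and 10.3% at resolution 0.5. From 2000 UMIs, wildtype late AM-like cells were 84.0% and IM-like cells 9.70%. At 20% mitochondrial UMIs, wildtype late AM-like cells were 83.0%, and IM-like cells 4.17% in wildtype early, 9.43% in HER2 early and 10.4% in HER2 late. The early AM-like spread was 0.126 over genes with at least 10 CPM, which adds counting error, and the late one 0.340 from 200 CPM and 0.235 without the length trend. The early IM-like spread, outside that tally, ranged from 0.184 (200 CPM) to 0.399 (10 CPM). Cells in cycle were 22.5, 22.6, 22.7 and 20.8% from 2 UMIs and 28.6, 24.5, 32.2 and 27.5% unthinned, since both lower the bar. Directions turned for Ftl1-ps1 with free RNA subtracted (0.04 in AM-like late, 4.22 in IM-like late, -4.42 in IM-like wildtype over stages), for Ccl12 (-0.34) and Ifi27l2a (-0.53) in IM-like early at 20% mitochondrial UMIs and (-0.45, -0.58) with the cluster of 1 library, and without cells holding 3 or more cell cycle UMIs for Lyz1 (-0.0466) and alternative activation (-0.0574) in IM-like early and Retnla (0.0944) and Mt2 (0.27) in IM-like late; the cause was not tested. Of 46 list results outside the percentiles, 27 stayed outside under every alternative run for them and 45 kept their direction. All 24 genes named for AM-like early kept direction and stayed within 1.5-fold of the main fold, against 21 and 13 of 24 for IM-like early. IM-like values are limited by depth, with 962495 UMIs in wildtype early.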

Other observations

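Several AM-like clusters were present in all 4 libraries. Cluster 19, led by the interferon-induced genes Isg15, Rsad2, Ifit1 and Irf7, held 0.209% of AM-like cells in wildtype early, 0.183% in HER2 early, 0.287% in wildtype late and 0.284% in HER2 late. Cluster 8, led by the replication genes Mcm6, Uhrf1 and Pcna, held 3.04, 3.04, 2.65 and 2.90%, and cluster 11, led by the mitotic genes Ube2c, Cenpf and Ccnb2, 1.54, 1.42, 1.99 and 2.02%. Cluster 12, led by Pclaf, Top2a and Rrm2, held 2.21, 1.67, 1.41 and 1.39%. Cluster 5, led by Cxcl2, Egr1, Osm and Ccl3, held 13.5, 9.23, 2.92 and 11.3%. Its low share in wildtype late was not particular to it, as clusters 2, 3 and 4 held 3.44, 4.93 and 2.85% there. Cluster 0 took 59.7% of those cells, and libraries were not integrated.

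Non-macrophage cells gave the same direction as AM-like cells for some lists in the late comparison of HER2 with wildtype. Their median log2 fold was 0.33 for stress genes, 0.14 for oxidative phosphorylation and -0.49 for cholesterol synthesis. AM-like cells had 0.27, 0.22 and -0.39 over the same members, and no value here is relative to all genes. More lists lay on opposite sides of 0 than on the same side. Among them were type I interferon response (-0.35 in AM-like, 0.40 in non-macrophage cells) and MHC class I presentation (-0.04 and 0.67). Late AM-like folds had a median of -0.165 over the 2608 genes used for the spread. An AM-like median between that value and 0, as for MHC class I, therefore does not show an opposite shift. The mix of non-macrophage cells also differed, with 80 T cell-like cells among 252 in wildtype late and 38 among 159 in HER2 late. A cluster of 33 cells, 32 of them from wildtype early, was led by Ly6i, Irf7, Apoe, Vcam1, Cd4 and Cxcl9.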
